A study of Mus musculus with 10 samples.

How the data were processed

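Tumour-infiltrating T cells of mouse colorectal carcinoma were measured in 10 samples: 5 libraries of single-cell RNA sequencing (Chromium 5' chemistry, per the labels) and 5 libraries of TCR sequencing of the same tumours. Per the labels the groups were untreated (2 libraries of each kind), S. chamaejasme (1 of each) and S. chamaejasme plus anti-PD-1 (2 of each, called the combination). The submitters' processing notes name Cell Ranger 3.1.0 with STAR on the mm10 genome; the annotation release and STAR's version are not given in the sources used here. The RNA files deposited by the authors hold raw UMI counts per gene and cell for 31053 features and the barcodes Cell Ranger called as cells, with no normalization. The TCR files deposited by the authors list assembled contigs with their counts of reads and UMIs, chain, gene segments, CDR3 and a clonotype identifier. Values were tested on the files for whole numbers and for the barcodes shared between matched libraries. No batch is given in the labels, and titles of untreated samples are styled differently from those of treated samples, so a batch that follows the groups cannot be told apart from treatment. The p values measure spread between samples, whether or not these came from separate animals.

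The RNA files held 22590 barcodes and 97967927 UMIs. Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept (21549). Scrublet (in scanpy 1.11.5, expected doublet rate 0.05) with its automatic threshold marked 17 of these cells, too few for the loading. After that was seen, the highest scores were removed at 0.8% per 1000 cells of a library (799 cells) together with cells holding at least 2 productive TRB chains (618 cells), 1310 cells in all. The remaining 20239 cells were normalized per cell, 2000 variable genes and 30 principal components were taken, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1, 15 neighbours, seed 0) gave 15 clusters. No integration between libraries was applied. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

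Clusters were named from marker lists of 20 cell types. A gene counted as detected in at least 10% of a cluster's cells. Treg-like clusters and types other than T-like ones needed at least 3 detected markers raised by a log2 fold of at least 1. CD8 and CD4 conventional T-like clusters needed no raised marker. They needed coreceptor genes that differed by at least a ratio of 2, with Cd8a and Cd8b1 or at least 3 CD4 conventional markers detected. All T-like clusters needed Cd3e, Cd3g and Trac detected. The 10 leading genes were ranked by fold with a pseudocount of 10 CPM. A T-like class could be compared when in each of its clusters these held no more markers of another type than of its own. The CD4 conventional T-like clusters all had 0 of their own markers among these genes. The marker lists were fixed in advance, but the pseudocount, the detection minimum, the raised fold, the coreceptor ratio, the 10% range that leaves out genes of flat detection and the rule that leaves a cluster unnamed when its leading genes go against its name were set after the clusters had been seen and before any contrast was computed. Of 12 settings of pseudocount and detection minimum looked at, all 3 T-like classes could be compared in 6 and not in 6 (CD8 in 12, CD4 conventional in 6, Treg in 11). The setting taken was chosen because it lets all 3 be compared. In 4 settings all 3 could be compared and the T-like clusters were also named as here. Every cluster was named as here in 2 settings. Clusters are therefore also compared by number. Cluster 2 of the CD8 T-like class had 2 of its own markers and 2 monocyte markers among its leading genes. Gamma delta T cells, the other class named, had 23 cells in 1 library, under the minimum of 30, and were compared in cell number but not in expression.

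UMI counts were summed per library over the cells of a class. The CD8 T-like sums held 1945919 to 4495517 UMIs from 469 to 776 cells, the CD4 conventional T-like sums 5497984 to 16496468 UMIs from 1493 to 3265 cells, and the Treg-like sums 515937 to 2895500 UMIs from 153 to 621 cells. Each class was fitted in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr by group, glmQLFit and glmQLFTest, two-sided) over all 5 libraries, which leaves 2 residual degrees of freedom. The lone S. chamaejasme library was assumed to vary like the others. The threshold was a Benjamini-Hochberg adjusted p under 0.05. SE is the absolute log2 change over the square root of the F statistic, and levels are CPM with SD over libraries. A fold against a group with 0 counts is a bound, computed against a floor of 3 counts over the group and written "at least"; with 1 to 3 counts in a group the ratio has its exact 95% counting interval. Shares of 1 library have 95% Wilson intervals. Intervals and floors cover counting error only. Cell numbers per class were tested with edgeR with library totals as offsets. The difference between the changes in CD8 and CD4 conventional T-like cells was tested as an interaction with the library as a block, and expanded against single-cell clones with the library as a block.

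In the TCR libraries 1725, 2953, 4395, 4713 and 4488 barcodes had a contig (untreated replicates 1 and 2, S. chamaejasme, combination replicates 1 and 2), and 1144, 2089, 3338, 3809 and 3679 cells had a productive TRA and TRB chain. A clone is the set of cells of a library with the same V genes and CDR3 nucleotide sequences of both chains, and is expanded at 2 or more cells. The share of cells in expanded clones was computed as the exact expectation when every library is thinned to 1144 cells. Groups were compared by an exact permutation test, two-sided, which with 2 against 2 libraries has 6 assignments and cannot give a p under 0.333.

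The 24 gene lists were T cell receptor complex, cytotoxicity, inhibitory receptors and exhaustion, naive and memory T cells, Treg identity and activation, T cell costimulation, T cell cytokines, chemokines and chemokine receptors, type I interferon response, interferon gamma and antigen presentation, proliferation, tissue residency, TCR signalling and immediate early genes, dissociation and heat shock, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded transcripts, unfolded protein response, apoptosis, and markers of myeloid, B cell, tumour epithelial, erythroid and stromal contamination. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a contrast, and again with a correlation estimated per list. With an estimated correlation camera uses the residual degrees of freedom of the fit, which were 2 in the fits between groups. Few lists could pass there whatever their change, so a list that does not hold in this way is neither supported nor contradicted by it. Named genes were, among genes past the threshold with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, those with the largest log2 change: 10 up and 10 down for CD8 T-like cells in combination against untreated and for expanded clones, 5 up and 5 down elsewhere. TCR and immunoglobulin segment genes, predicted genes, ribosomal, mt-, Xist and Y-linked genes were left out of that ranking. To these were added a panel of 13 genes (among them Pdcd1, Havcr2, Lag3, Tigit, Ctla4, Tox, Tcf7, Gzmb, Prf1, Ifng, Mki67 and Foxp3) and up to 4 members of each list with the smallest p. Some of these genes are not reported here. The contrasts, tests, lists, markers, the rule for named genes and the first set of alternative settings below were chosen before the data were examined. Gene positions come from GENCODE M21 on GRCm38, in which 121 of 121 named genes were found.

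Settings fixed in advance were DESeq2's size factors within edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, stricter cells (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions of 0.6 and 1.5, cells gated on a TRB contig and coreceptor UMIs in place of clusters, only the libraries compared, each library left out, other definitions of clones and expansion, and the estimated correlation. Chosen after seeing the data were each cluster alone, CD4 conventional T-like cells without clusters 3, 6 and 11, sums without droplets of at least 100 haemoglobin UMIs, and the number of cells that carry the counts of each named gene. The fits were tested on simulated data with known changes: edgeR recovered 73% of 2-fold and 92.8% of 4-fold changes in CD8 T-like cells between combination and untreated, with 2.98% false calls, 74% and 99.0% in CD4 conventional T-like cells (6.59% false) and 56.6% and 91.7% in Treg-like cells (2.04% false). DESeq2 recovered 39% and 73% in CD8 T-like cells with 0% false calls. The simulated libraries shared 1 expression profile apart from the known changes, and a gene's spread was the same in every library. They held no differing cluster mixtures and no unequal spread between groups. The real untreated pair differed more (chi-square per gene 15.027) than the combination pair (4.314), so these rates need not hold for the real data.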

Results

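Tumour-infiltrating T cells of mouse colorectal carcinoma were profiled by droplet single-cell RNA sequencing from the 5' end of transcripts, and the T cell receptor (TCR) chains of the same cells were sequenced in matched libraries. The labels put 5 RNA libraries and 5 TCR libraries into 3 groups. The untreated group had 2 libraries of each kind, the group given S. chamaejasme (Stellera chamaejasme, a flowering plant) had 1 of each, and the group given S. chamaejasme with an antibody against the inhibitory receptor PD-1, called the combination here, had 2 of each. No group received anti-PD-1 alone, so no comparison separates the antibody from the plant with replicates on both sides. The labels do not state whether replicates came from separate animals. The RNA libraries held 8763821 and 15428707 UMIs (untreated replicates 1 and 2), 19999977 UMIs (S. chamaejasme) and 27759543 and 26015879 UMIs (combination replicates 1 and 2). After filtering, 2244, 3505, 5044, 4876 and 4570 cells remained in that order, with medians of 3522, 3915, 3403.5, 4905.5 and 4830.5 UMIs per cell.

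The 20239 cells fell into 15 clusters, and 10 of these were named as 1 of 3 T cell classes from markers fixed in advance. CD8 T-like cells formed cluster 0, led by the chemokine gene Ccl5 and by Gzma, Gzmk, Gzmb and Ifng, and cluster 2, led by Ly6c2, Ly6a, Eomes and Dapl1. CD4 conventional T-like cells formed 6 clusters. Among these, cluster 10 was led by the cytokine genes Il17a, Il22 and Il17f, and cluster 8 by Tox2, Tnfsf8 and Il21. Clusters 3, 4 and 6 had Igfbp4 among their leading genes, and cluster 6 was led by Ifngr2 and Klhdc2. Cluster 11 was led by Plaur, with Bbc3, Lars2 and AY036118 among its leading genes. Treg-like cells formed cluster 9 (Penk, Tnfrsf9, Il10, Foxp3, Areg) and cluster 12 (Lrrc32, Gpr83, Foxp3, Il2ra). Cluster 13 held 204 gamma delta T cells with Trdv4 and Cd163l1. Clusters 1, 5, 7 and 14 stayed unnamed: cluster 1 (791 cells) was led by Xcl1, Fcer1g, Tyrobp and Trgv2, cluster 5 had a median of 1016 UMIs, cluster 7 was led by the cell cycle genes Pclaf, Stmn1 and Mki67, and cluster 14 by Jchain, Cd74 and Lyz2. Unnamed cells made up 4.72% and 6.51% of the untreated libraries, 14.8% of the S. chamaejasme library and 6.26% and 6.15% of the combination libraries. They are in none of the class sums. Cluster 7 held 0.668% and 0.885% of the untreated libraries, 0.753% with S. chamaejasme and 0.861% and 2.47% of the combination libraries.

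The clusters that held most of a class differed between groups, so class sums compared between groups were sums over different mixtures. Cluster 0 held 59.7% and 37.4% of the CD8 T-like cells in untreated replicates 1 and 2, 70.4% with S. chamaejasme and 26.8% and 31.3% in combination replicates 1 and 2. Among CD4 conventional T-like cells, cluster 11 held 23.6% and 35% in the untreated libraries, 1.53% with S. chamaejasme and 2.88% and 2.65% in the combination. Cluster 6 held 4.82% and 5.51% in the untreated libraries, 17.8% with S. chamaejasme and 33.0% and 33.7% in the combination. Cluster 10 held 29.5%, 12.1%, 24.2%, 6.98% and 6.62% in the same order. In Treg-like cells, cluster 9 held between 60.8% and 77% in all 5 libraries. Transcripts of AY036118, a lincRNA, and of Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, were higher in untreated sums of all 3 classes. AY036118 had 2452 to 3717 CPM (UMI counts scaled to a common library size) in untreated sums, 608 to 771 with S. chamaejasme and 672 to 1195 in the combination. The predicted gene Gm42418 went the same way at a higher level, with 11798 to 23154 CPM in untreated sums. It had 5862 to 7160 CPM with S. chamaejasme and 6823 to 8864 in the combination. Whether these transcripts follow treatment or the quality of the libraries was not tested.

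**Figure D1:**
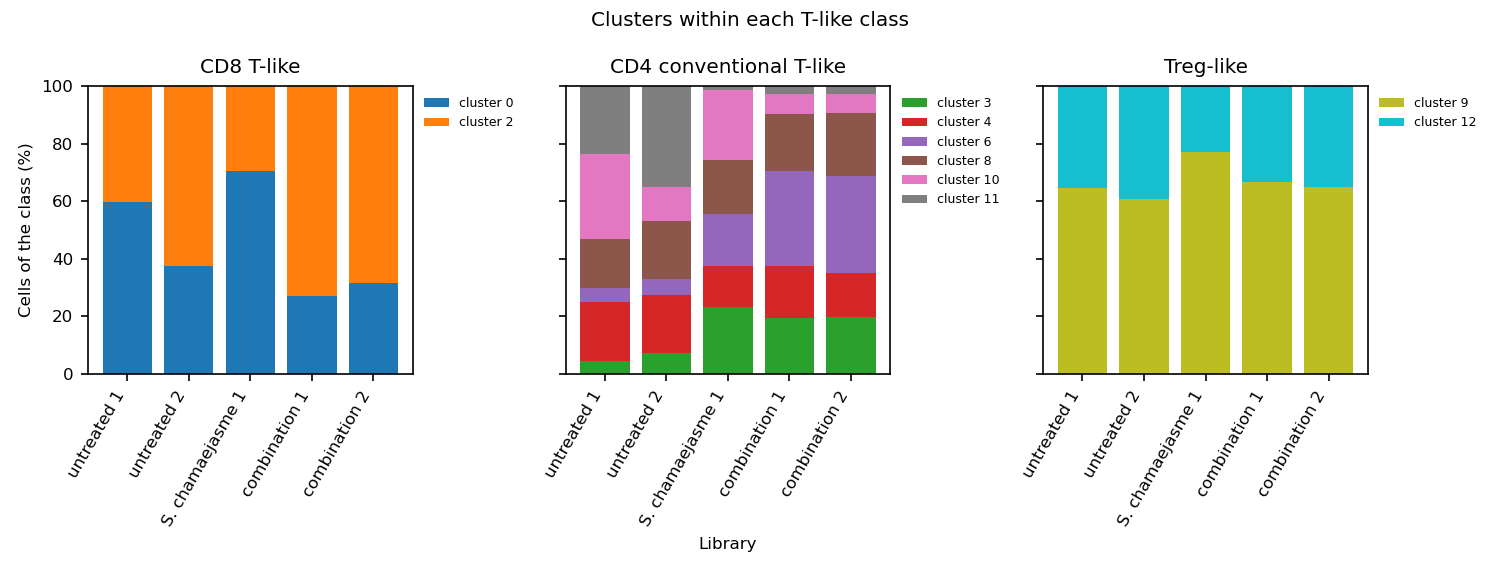
Share of each cluster among the cells of each T-like class, in percent, with 1 stacked bar per library (combination: S. chamaejasme plus anti-PD-1). Cluster 11 holds 23.6% and 35% of the CD4 conventional T-like cells in the untreated bars and at most 2.88% in the others.

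The first comparison asked whether the treatments went with another make-up of the infiltrate. CD4 conventional T-like cells were 66.5% and 65.8% of the untreated libraries and 67.0% and 63.5% of the combination libraries. CD8 T-like cells were 20.9% and 15.3% against 13.5% and 16.8%, and Treg-like cells 6.82% and 11.4% against 12.7% and 12.8%. Gamma delta T cells, cluster 13 alone, were 1.03% and 0.97% against 0.51% and 0.77%. Cluster 1 also met the marker rule for gamma delta T cells but stayed unnamed for its leading genes. It held 0.980% and 2.71% of the untreated libraries, 9.32% with S. chamaejasme and 2.58% and 1.71% of the combination libraries, so gamma delta shares depend on leaving it out. The S. chamaejasme library held 57.0% CD4 conventional T-like cells (95% Wilson interval 55.7% to 58.4%), 15.4% CD8 T-like cells (14.4% to 16.4%) and 11.1% Treg-like cells (10.3% to 12%). With edgeR on cell numbers, 0 of 5 classes passed the threshold between combination and untreated, and 0 had an unadjusted p under 0.05. The largest log2 differences were -0.64 for gamma delta T cells (adjusted p = 0.396) and 0.47 for Treg-like cells (adjusted p = 0.396). Without untreated replicate 2, the log2 difference was 0.90 for Treg-like cells and 0.39 for the unnamed cells, which count as 1 of the 5 classes.

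In CD8 T-like cells, the killer cells of the infiltrate, the combination was compared with untreated tumours to see which programmes moved. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031 on the minus strand of GRCm38), which encodes the interferon-inducible surface protein Sca-1, rose by 1.73 ± 0.25 (log2, SE), from 17.8 ± 0.844 to 59.3 ± 20.4 CPM (SD, n = 2 against 2). Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193, plus strand), the alpha chain of the interleukin 2 receptor made by activated T cells, fell by 2.41 ± 0.25, from 28.1 ± 5.3 to 5.23 ± 0.412 CPM. Its change was -1.71 in cluster 0 alone, and it could not be tested in cluster 2. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand), the cytotoxic protease granzyme B, fell by 1.85 ± 0.35, from 718 ± 501 to 198 ± 25 CPM. The 2 untreated libraries stood at 1072 and 364 CPM, and the Gzmb change was -0.88 without untreated replicate 1 and -0.99 in cluster 0 alone, while DESeq2 did not call it. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand), which encodes PD-1, stood at 30.5 ± 6.3 against 26.6 ± 5.21 CPM (log2 difference 0.19 ± 0.21, adjusted p = 0.631). Its change was 0.78 in cluster 0 alone (edgeR adjusted p = 0.102) and 2.18 in cluster 2 alone (adjusted p = 0.429).

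Other genes named as higher in the CD8 T-like cells of the combination were Ms4a4c, Tbxa2r, Ephx1, St6gal1, Tapbp, Ly6c2, Tec and Slc25a11, with log2 changes of 1.59 (Ms4a4c) to 1.03 (Slc25a11). Tapbp (chromosome 17, 33915899 to 33929292, plus strand) encodes tapasin, which loads peptides on MHC class I, and rose from 61.3 ± 9.12 to 128 ± 14.1 CPM (adjusted p = 0.00312). Ly6c2 and Ms4a4c also stood on the list of monocyte markers, and Ly6c2 was a leading gene of cluster 2. The genes named as lower were Ifitm3 (-2.53), Furin (-2.06), the hexokinase gene Hk2 (-2.04), Lmna (-2.01), Lilrb4a (-2.01), Sytl3 (-1.98), the cell cycle inhibitor gene Cdkn1a (-1.98) and Lilr4b (-1.88). Furin (ENSMUSG00000030530, chromosome 7, 80388585 to 80405436, minus strand), a protein convertase induced by T cell activation, fell from 73.6 ± 10.1 to 17.5 ± 2.81 CPM (adjusted p = 0.000195). Of the fixed panel, the inhibitory receptor gene Tigit fell by 0.67 ± 0.13 (adjusted p = 0.0152), but stood at -0.22 in cluster 0 (adjusted p = 0.573) and 0.069 in cluster 2 (adjusted p = 0.918). Lag3 (0.56, adjusted p = 0.166), Tox (0.47, adjusted p = 0.13), Ctla4 (-0.28), Tcf7 (0.24), Prf1 (0.37), Ifng (-0.53, adjusted p = 0.13) and Mki67 (-2.63, adjusted p = 0.0766) did not pass. Havcr2 had 3 counts in the combination and 16 in untreated sums, a ratio of 0.0973 (95% counting interval 0.0182 to 0.34), and did not pass. In cluster 0 alone, Lag3 (1.20, edgeR adjusted p = 0.019) and Tox (1.10, adjusted p = 0.0101) passed as higher. In cluster 2 Tox stood at 0.076 and Lag3 could not be tested.

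**Figure D2:**
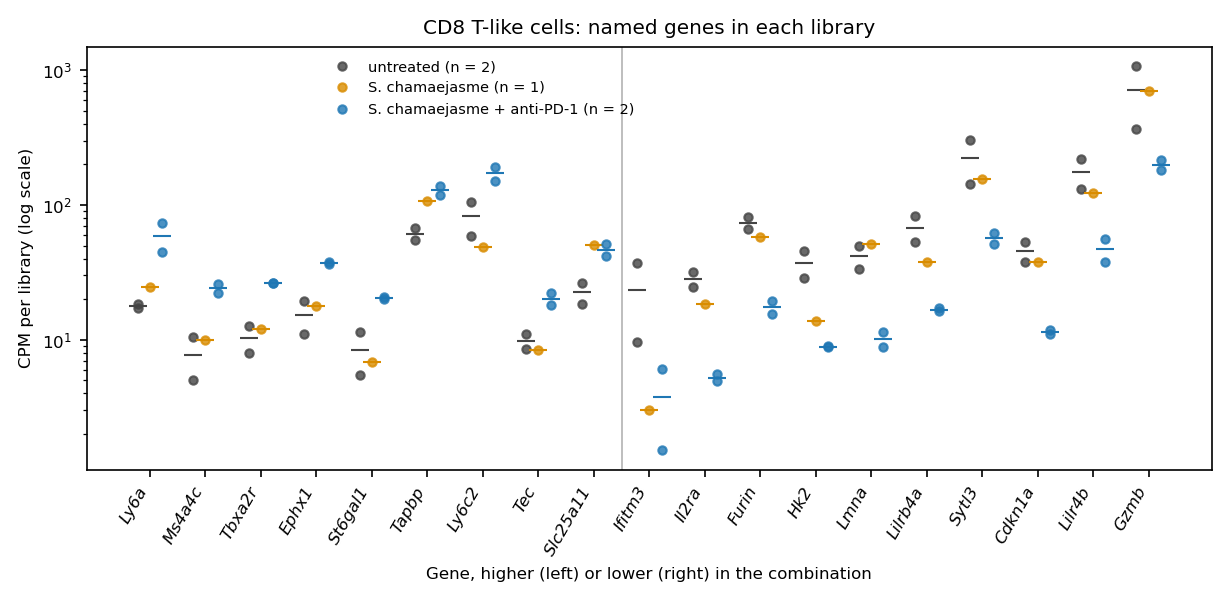
Expression in CD8 T-like sums of 19 of the 20 genes with the largest changes between combination and untreated, in CPM on a log axis, with 1 point per library and a dash at each group mean. For Ly6a the combination points (mean 59.3 CPM) lie above the untreated points (mean 17.8 CPM), and for Il2ra they lie below (means 5.23 and 28.1 CPM).

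Among lists fixed in advance, the naive and memory list tested as higher in CD8 T-like cells of the combination. Of 17 measured members 4 rose and 0 fell (4 and 0 adjusted over the list alone), with S1pr1 at 0.77 and Slamf6 at 0.76 (adjusted p = 3.96e-07 by camera, adjusted p = 0.461 with an estimated correlation). Interferon gamma and antigen presentation genes had 5 of 36 up and 1 down (6 and 2 adjusted over the list alone), among them Tap2 at 0.87 and Psmb9 at 0.59 (adjusted p = 0.0018, and 0.461 with an estimated correlation). Type I interferon genes had 2 of 28 up and 0 down (4 and 0 adjusted over the list alone), among them Zbp1 at 0.59 (adjusted p = 0.00326, and 0.482 with an estimated correlation). The apoptosis list tested as lower, with 10 of 28 lower and 0 higher (11 and 1 adjusted over the list alone), among them Bbc3 (-1.14), a promoter of cell death, and Bcl2l1 (-1.48) and Bcl2a1b (-1.17), which protect from it (adjusted p = 3e-08, and 0.397 with an estimated correlation). Tissue residency genes had 3 of 14 down and 0 up (6 and 0 adjusted over the list alone), with Cxcr6 at -1.03 (adjusted p = 0.000557, and 0.469 with an estimated correlation); Cxcr6 stood at -0.35 in cluster 0 (adjusted p = 0.308) and -0.29 in cluster 2 (adjusted p = 0.808). TCR signalling and immediate early genes had 5 of 21 down, with Nr4a3 at -1.21 and Nfkbia at -0.97, and 1 up, Fos at 0.72 (9 and 1 adjusted over the list alone; adjusted p = 0.000557, and 0.461 with an estimated correlation). Inhibitory receptor and exhaustion genes had 4 of 18 down and 0 up (6 and 1 adjusted over the list alone), among them Bhlhe40 (-1.26), Tigit and Prdm1 (-1.33), with adjusted p = 0.0145, and 0.461 with an estimated correlation. No list was tested within a single cluster. In cluster 0 alone Lag3 (1.20) and Tox (1.10) passed edgeR's threshold as higher, while Bhlhe40 (-0.54), Prdm1 (-0.77) and Tigit (-0.22) stood lower and did not pass. The fall of this list in the class is therefore not shown for the cells of cluster 0. AY036118, Lars2 and the cell shares of clusters 0 and 2, given above, moved with the same groups of libraries.

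T cell cytokine genes had 2 of 11 lower in the CD8 T-like cells of the combination, Tnfsf14 (-1.79) and Tnf (-0.86), and 1 higher, Il10, with 36 counts (in 10 cells) against 0 and thus at least 6.23-fold higher (4 and 1 adjusted over the list alone; adjusted p = 0.0478, and 0.461 with an estimated correlation). The Treg identity and activation list had 1 of 12 up, Il10, and 1 down, Il2ra (1 and 2 adjusted over the list alone). Its median (-0.36) and its test (adjusted p = 0.0312, and 0.469 with an estimated correlation) were negative and its mean (0.16) positive. The remaining lists did not pass the threshold. Cytotoxicity had 3 of 15 down, Gzmb, Klrc1 (-1.05) and Srgn (-0.79), and 0 up (3 and 0 adjusted over the list alone; adjusted p = 0.0822), with a median of 0.02 against a mean of -0.38. Costimulation had 1 of 14 up, Cd27 at 0.82, and 2 down, Cd44 at -0.82 and Cd28 at -0.57 (2 and 4 adjusted over the list alone; adjusted p = 0.0822). Chemokines and their receptors had 1 of 12 down (3 adjusted over the list alone), glycolysis and hypoxia 3 of 28 down (5 adjusted over the list alone), the unfolded protein response 2 of 19 down (2 adjusted over the list alone), mitochondrially encoded transcripts 1 of 13 down (1 adjusted over the list alone), and dissociation and heat shock 2 of 22 down and 1 up (2 and 1 adjusted over the list alone). None of the 12 T cell receptor complex, 23 proliferation and 57 oxidative phosphorylation genes passed edgeR's threshold in this contrast, over all genes or adjusted over the list alone. Their adjusted p values by camera were 0.287, 0.0822 and 0.507. Cells of cluster 7, which is led by cell cycle genes and stayed unnamed, lie outside every class sum. Proliferation, Mki67 included, was therefore tested without them.

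In CD8 T-like cells between combination and untreated, camera called 9 of 19 lists, of which 0 held with an estimated correlation. At 2 residual degrees of freedom few lists could hold, so this 0 decides little. In total, edgeR called 442 of 9634 genes in this contrast, 126 higher and 316 lower. Without 1 library the count was 1001 (untreated replicate 1), 1597 (untreated replicate 2), 139 (combination replicate 1) and 229 (combination replicate 2). DESeq2 called 129 genes, cluster 0 alone gave 280 and cluster 2 alone 172, and Ly6a changed by 0.04 in cluster 0 (adjusted p = 0.981) against 1.73 in cluster 2 (adjusted p = 0.000378). Of the genes given above, Tbxa2r, Tec, Tigit, Klrc1, Prdm1, S1pr1, Cd44, Cd28, Tnf, Cxcr6 and Bcl2a1b passed in neither cluster, nor did St6gal1, which could be tested in cluster 2 alone (0.85, adjusted p = 0.12). Some of them kept much of their change in clusters 0 and 2, as Tec (0.97 and 0.76, against 1.04 in the class) and Prdm1 (-0.77 and -0.84, against -1.33) did. For Tigit, Cxcr6 and Klrc1 (-0.47 and 0.98, against -1.05) little was left or the sign turned in 1 of the clusters. Smaller falls than in the class were also left in clusters 0 and 2 for Cd44 (-0.36 and -0.28), Cd28 (-0.16 and -0.43), Tnf (-0.36 and -0.71) and Bcl2a1b (-0.63 and -0.48). Cluster shares stay open as a cause for these genes and are not settled for the others that passed in neither cluster.

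Against untreated tumours, CD8 T-like cells of the S. chamaejasme library (n = 1, against n = 2) carried more Ifng and Cd40lg; cluster 0 also held a larger share of them, as given above. Ifng, the cytokine interferon gamma, rose by 1.22 ± 0.21 (SE), from 143 ± 40.9 to 331 CPM (adjusted p = 0.0237), and Cd40lg, the ligand through which T cells help other cells, rose by 1.42 ± 0.21, from 23.2 ± 4.64 to 62.5 CPM. Qpct (2.18), Smpd5 (1.91), Izumo4 (1.57) and Snai3 (1.55) completed the named genes that rose. Lars2 (-2.39), AY036118 (-2.28), the histone gene Hist1h2ap (-2.11), Rgs16 (-1.81) and the cell death gene Bbc3 (-1.77) were those that fell. Gzmb stood at 700 against 718 ± 501 CPM and Pdcd1 at 11.4 against 26.6 ± 5.21 CPM (-1.24, adjusted p = 0.059). Cytotoxicity genes had 2 of 15 up, Nkg7 (0.69) and Ctsw (0.68), and 0 down (5 and 1 adjusted over the list alone; adjusted p = 0.0159, and 0.736 with an estimated correlation). Mitochondrially encoded transcripts had 2 of 13 down, mt-Nd3 (-1.85) and mt-Co3 (-1.09), and 0 up (3 and 0 adjusted over the list alone; adjusted p = 0.00108, and 0.736 with an estimated correlation). The proliferation list tested as lower with 0 of 23 members called over all genes or adjusted over the list alone (adjusted p = 0.0159, and 0.736 with an estimated correlation). In all, edgeR called 180 genes, 74 higher and 106 lower. The count was 1406 without untreated replicate 1 and 1100 without untreated replicate 2, and DESeq2 called 86; the lone library was assumed to vary like the others.

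Set against S. chamaejasme alone, the combination went with more Myb and less Ifng in CD8 T-like cells (n = 2 against 1). Cluster 0 held 70.4% of these cells with S. chamaejasme and 26.8% and 31.3% in the combination replicates. Ifng was a leading gene of cluster 0, and Ly6c2 and Ppic were leading genes of cluster 2. Single clusters were not tested in this contrast, so cluster shares stay open as a cause of the gene and list changes below. Myb, a transcription factor of stem-like T cells, rose by 2.84 ± 0.42, from 3.29 to 23.8 ± 3.15 CPM, and Ly6c2 by 1.81 ± 0.28, from 48.8 to 172 ± 28.4 CPM. Pdcd1 rose by 1.43 ± 0.28, from 11.4 to 30.5 ± 6.3 CPM (adjusted p = 0.0346), and Ifng fell by 1.75 ± 0.21, from 331 to 97.9 ± 16.4 CPM (adjusted p = 0.00288). Ppic (2.37), Pde2a (1.77) and Sidt1 (1.55) also rose, and Qpct (-2.37), Lmna (-2.33), Fgl2 (-2.08), Nebl (-1.99) and Cd40lg (-1.93) fell. Naive and memory genes had 3 of 17 up and 0 down (12 and 0 adjusted over the list alone), with S1pr1 at 1.33 (adjusted p = 8.82e-14, and 0.414 with an estimated correlation). Tissue residency had 3 of 14 down and 0 up (1 up and 10 down adjusted over the list alone), with Cxcr6 at -1.50 and Itga1 at -1.42 (adjusted p = 4.33e-10, and 0.414 with an estimated correlation). Cytotoxicity had 2 of 15 down, Klrc1 at -1.22 and Fasl at -1.48 (1 up and 7 down adjusted over the list alone; adjusted p = 6.75e-07, and 0.414 with an estimated correlation). T cell cytokines had 2 of 11 down, Ifng and Tnf (-1.31), with 1 up and 6 down adjusted over the list alone (adjusted p = 3.92e-06, and 0.414 with an estimated correlation). A total of 131 genes passed in edgeR, 47 higher and 84 lower, and 12 of 19 lists, of which 0 held with an estimated correlation. Without untreated replicate 1 the count was 1096 and without untreated replicate 2 it was 1099, and DESeq2 called 80 genes.

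In CD4 conventional T-like cells, helper cells other than Treg-like cells, the combination went with more Pdcd1 and fewer transcripts of interleukin 22 than in untreated tumours. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047, plus strand), a cytokine that acts on epithelia, fell by 3.14 ± 0.37, from 379 ± 190 to 42.8 ± 16.8 CPM (n = 2 against 2, adjusted p = 0.0103). Pdcd1 rose by 1.69 ± 0.25, from 10.3 ± 4.55 to 34.7 ± 6.06 CPM (adjusted p = 0.0157). Igsf23 (1.31), the interferon-induced GTPase gene Tgtp2 (1.22), Myo6 (1.18) and Sidt1 (1.08) rose as well. Hk2 (-2.57), Serpinb1a (-2.47), Lilr4b (-2.43) and Gzmb (-2.23, from 38.5 ± 28.8 to 7.9 ± 1.88 CPM) fell. Il13, a type 2 cytokine, had 98 counts in the combination (in 11 of 6167 cells) and 1 in untreated sums, a ratio of 45.9 (95% counting interval 8.06 to 1833). Tigit (-0.37, adjusted p = 0.0532), Ctla4 (-0.35), Lag3 (0.73) and Prf1 (0.90, adjusted p = 0.0631) did not pass. Il22, Serpinb1a and Lilr4b were leading genes of cluster 10 and Igsf23 of cluster 6, whose shares of the class differed between the groups.

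In the CD4 conventional T-like cells of the combination, the interferon gamma and antigen presentation list had 10 of 36 up and 0 down (14 and 0 adjusted over the list alone), with Tapbp at 0.90 and Psmb9 at 0.66 (adjusted p = 4.08e-07, and 0.455 with an estimated correlation). The type I interferon list had 5 of 32 up and 0 down (8 and 0 adjusted over the list alone), with Rtp4 at 1.04 and Zbp1 at 0.69 (adjusted p = 1.1e-06, and 0.455 with an estimated correlation), and naive and memory genes 4 of 16 up and 0 down (6 and 0 adjusted over the list alone), with Slamf6 at 0.67 and S1pr1 at 0.45 (adjusted p = 0.000315, and 0.455 with an estimated correlation). Tissue residency had 4 of 12 down and 0 up (7 and 0 adjusted over the list alone), with Cxcr6 at -1.53 and Prdm1 at -1.45 (adjusted p = 2.01e-06, and 0.455 with an estimated correlation). Apoptosis had 10 of 28 down and 0 up (14 and 2 adjusted over the list alone), with Bbc3 at -1.12 (adjusted p = 2.76e-07, and 0.455 with an estimated correlation). Chemokines and their receptors had 2 of 17 down and 0 up (7 and 1 adjusted over the list alone), with Ccr4 at -1.03 (adjusted p = 0.0212, and 0.455 with an estimated correlation), and dissociation and heat shock genes 2 of 22 down, among them Hspa1b (-0.87), and 1 up, Fos (0.80), with 7 down and 2 up adjusted over the list alone (adjusted p = 0.0425, and 0.455 with an estimated correlation). Mitochondrially encoded transcripts had 1 of 13 down, mt-Nd3 at -1.36 (1 adjusted over the list alone; adjusted p = 0.0267, and 0.651 with an estimated correlation). Of the cell types that could contaminate the sums, 8 myeloid genes had 1 up, Ctss (0.66), and 1 down, Apoe (-1.35, but 1.67 with cells gated on TCR and coreceptor), with 3 and 2 adjusted over the list alone (adjusted p = 0.243), and 5 erythroid genes had 0 called over all genes by edgeR and 0 adjusted over the list alone (adjusted p = 0.548). Bbc3 was a leading gene of cluster 11, together with Lars2 and AY036118.

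The count in CD4 conventional T-like cells was 749 of 11362 genes by edgeR, 274 higher and 475 lower, and 8 of 21 lists, of which 0 held with an estimated correlation. It was 2301 without untreated replicate 1, 2513 without untreated replicate 2, 251 without combination replicate 1 and 207 without combination replicate 2, and DESeq2 called 419. The class itself rests on a naming choice made after the clusters were seen; its clusters 3, 4, 6, 8, 10 and 11 gave 68, 262, 134, 111, 74 and 103 genes alone, and the class without clusters 3, 6 and 11 gave 486. Of the genes given above, Tgtp2, Myo6, Serpinb1a, Lilr4b, Gzmb, Prdm1, S1pr1, Ccr4, Cxcr6, Rtp4, Ctss and Apoe passed in none of the clusters in which they could be tested, and Cxcr6 stood at 1.25 in cluster 8 and 0.062 in cluster 10. Il22 fell in cluster 10 as well (-1.76).

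With S. chamaejasme alone, CD4 conventional T-like cells carried more of the cytotoxic granule gene Nkg7, at 54.6 CPM against 17.7 ± 2.51 in untreated sums (1.64 ± 0.23, n = 1 against 2, adjusted p = 0.0326). Haemoglobin transcripts, products of red blood cells, appeared in that library: Hba-a1 had 1252 counts, 1251 of them in 1 cell, against 0 (at least 554-fold higher), Hba-a2 was at least 408-fold higher, Hbb-bt had 762 counts against 2 (ratio 506, 95% counting interval 140 to 4186), and Hbb-bs rose by 9.32 ± 0.47. AY036118 (-2.15), Hist1h2ap (-2.12), Lars2 (-2.09), Zcchc9 (-1.44) and Amd2 (-1.44) fell. Pdcd1 stood at 29.7 against 10.3 ± 4.55 CPM (1.47, adjusted p = 0.0529). The erythroid list had 4 of 5 up and 0 down (5 and 0 adjusted over the list alone), with a median of 9.32, or 8.87 with genes at 0 set at their bounds (adjusted p = 6.51e-128, and 0.153 with an estimated correlation). Mitochondrially encoded transcripts had 2 of 13 down, mt-Nd3 (-1.66) and mt-Nd6 (-1.11), and 0 up (3 and 0 adjusted over the list alone; adjusted p = 0.00267, and 0.864 with an estimated correlation). Cytotoxicity had 1 of 14 up, Nkg7 (3 up and 1 down adjusted over the list alone; adjusted p = 0.0461, and 0.843 with an estimated correlation). The unfolded protein response list tested as lower with 0 of 21 members called over all genes by edgeR and 2 down adjusted over the list alone (adjusted p = 0.0398, and 0.843 with an estimated correlation). By edgeR 213 genes passed, 82 higher and 131 lower. The count was 2429 without untreated replicate 1, 1940 without untreated replicate 2 and 136 without combination replicate 2.

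Between combination and S. chamaejasme, CD4 conventional T-like cells differed at 24 genes by edgeR, 3 higher and 21 lower (n = 2 against 1). The named genes were Snhg6, which rose by 1.32 ± 0.17 from 10.8 to 27 ± 1.13 CPM, and the haemoglobin genes Hba-a2 (at least 871-fold lower), Hbb-bt (at least 720-fold lower), Hba-a1 (1 count against 1252, ratio 0.000282, 95% counting interval 7.13e-06 to 0.00157) and Hbb-bs (-11.34). Lgals3, which encodes galectin 3, fell by 2.50 ± 0.32, from 85.4 to 15.1 ± 0.0781 CPM. Cytotoxicity genes had 1 of 14 down, Nkg7 at -2.12 (1 up and 4 down adjusted over the list alone; adjusted p = 3.62e-07, and 0.255 with an estimated correlation). Type I interferon genes had 0 of 32 called over all genes and 6 up adjusted over the list alone (adjusted p = 3.42e-07, and 0.321 with an estimated correlation). Apoptosis had 3 of 28 down, Cdkn1a (-1.86), Bcl2a1d (-1.19) and Bcl2a1b (-1.05), with 1 up and 8 down adjusted over the list alone (adjusted p = 3.18e-06, and 0.254 with an estimated correlation). The erythroid list had 4 of 5 down (5 adjusted over the list alone), with a median of -11.37, or -9.77 with genes at 0 set at their bounds (adjusted p = 1.03e-256), and was the 1 of 15 lists called here that held with an estimated correlation (adjusted p = 0.0459). All 6899 haemoglobin UMIs of the S. chamaejasme sum lay in 2 of its 2877 cells, and 1 of these held all but 1 UMI, so this call rests on 1 droplet. DESeq2 called 89 genes, and the count was 1157 without untreated replicate 1, 1089 without untreated replicate 2, 98 without combination replicate 1 and 45 without combination replicate 2.

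In Treg-like cells, which restrain other T cells, the combination went with more Pdcd1 and Areg than in untreated tumours (n = 2 against 2). Pdcd1 rose by 1.10 ± 0.16, from 104 ± 0.695 to 223 ± 25.9 CPM (adjusted p = 0.00571), and Areg, which encodes the tissue repair factor amphiregulin, rose by 1.46 ± 0.20, from 117 ± 11.2 to 325 ± 95.2 CPM (adjusted p = 0.00317). Ly6a (1.88), the lactate transporter gene Slc16a3 (1.66), the receptor kinase gene Axl (1.58), Pqlc3 (1.56) and Pigs (1.55) rose. AY036118 (-1.78), Bbc3 (-1.56), Perp (-1.55), Irs2 (-1.42) and Etaa1 (-1.38) fell. Within clusters 9 and 12 alone, Ly6a, Axl, Pqlc3, Pigs, Perp, Irs2 and Etaa1 passed in neither where tested, and Areg was at 1.59 in cluster 9 and -0.065 in cluster 12 (adjusted p = 0.956). Foxp3, the transcription factor that defines Treg cells, stood at 260 ± 10.4 against 203 ± 47.4 CPM (0.40, adjusted p = 0.224), and Ctla4 changed by 0.42 (adjusted p = 0.114). Type I interferon genes had 1 of 22 up, Zbp1 at 1.11, and 0 down (7 and 0 adjusted over the list alone; adjusted p = 2.24e-06), and interferon gamma and antigen presentation genes 2 of 36 up, Tap2 (0.73) and Gbp6 (81 counts against 3, ratio 9.0, 95% counting interval 2.97 to 44.6), with 11 up and 0 down adjusted over the list alone (adjusted p = 2.84e-05). Both lists had adjusted p = 0.307 with an estimated correlation. TCR signalling genes had 2 of 21 up, Fos (1.09) and Dusp1 (0.69), with 3 adjusted over the list alone (adjusted p = 0.00851, and 0.688 with an estimated correlation). The Treg identity list had 1 of 20 up, Areg, with 3 adjusted over the list alone (adjusted p = 0.0202, and 0.663 with an estimated correlation). In all 170 of 8943 genes passed in edgeR, 64 higher and 106 lower, and 7 of 19 lists, of which 0 held with an estimated correlation. With no filter on low counts 0 genes passed in edgeR (1609 at an unadjusted p under 0.05) and DESeq2 called 34. Leaving out 1 library gave 1110 (untreated replicate 1), 476 (untreated replicate 2), 61 (S. chamaejasme), 28 (combination replicate 1) and 38 (combination replicate 2).

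Treg-like cells of the S. chamaejasme library also carried more Pdcd1, at 227 against 104 ± 0.695 CPM (1.12 ± 0.19, n = 1 against 2, adjusted p = 0.0104), and more Areg, at 469 against 117 ± 11.2 CPM (1.99 ± 0.23, adjusted p = 0.000352). Tnfsf11, the cytokine RANKL, rose by 2.18 ± 0.34, from 11.4 ± 0.0392 to 51.8 CPM, and Rapsn (2.19) and Lgmn (2.10) rose. Jchain, a gene of antibody-secreting cells, was higher by 4.60 ± 0.39, from 5.23 ± 3.38 to 102 CPM, but 153 of its 168 counts lay in 1 of 560 cells; cluster 14, led by Jchain, made up 0.575% of this library and 0.175% to 0.308% of the others. Il22 had 47 counts, 46 of them in 1 cell, against 1 (ratio 55.3, 95% counting interval 9.45 to 2231), and its direction turned with cells gated on TCR and coreceptor. Ccl4 (-3.03, but 0.65 with doublets kept and 2.66 with the gate, and with 38 of 60 untreated counts in 1 cell), AY036118 (-2.12), Hist1h2ap (-2.06), Thap12 (-1.90) and Znhit3 (-1.77) fell. TCR signalling and immediate early genes had 6 of 21 up and 0 down (11 and 0 adjusted over the list alone), with Fos at 1.58 and Dusp1 at 1.32 (adjusted p = 1.94e-12, and 0.389 with an estimated correlation). The Treg identity list had 1 of 20 up, Areg (7 up and 1 down adjusted over the list alone; adjusted p = 9.67e-06, and 0.389 with an estimated correlation), and dissociation and heat shock genes, which share Fos and Dusp1 with the TCR list, 4 of 22 up (9 up and 2 down adjusted over the list alone; adjusted p = 5.13e-05, and 0.389 with an estimated correlation). The total was 111 genes, 68 higher and 43 lower, and 8 of 19 lists, of which 0 held with an estimated correlation. Without untreated replicate 1 it was 967 and without untreated replicate 2 it was 518, while DESeq2 called 59 and edgeR with no filter on low counts 7.

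Between combination and S. chamaejasme, Treg-like cells differed in Gpm6b, with 123 counts against 0 (at least 11.6-fold higher, n = 2 against 1), and in Jchain, lower by -4.73 ± 0.30, from 102 to 3.81 ± 2.01 CPM, with 153 of the 168 S. chamaejasme counts in 1 cell. Serpina3i (2.53), Nrn1 (2.21), Dtx1 (1.82) and Il1r2 (1.26), a decoy receptor for interleukin 1, rose. Il22 (at least 55.3-fold lower, again from 1 cell with 46 counts, and 1.68 in log2 with cells gated on TCR and coreceptor), Lmna (-2.12), AA467197 (-1.89) and Npnt (-1.78) fell. Pdcd1 stood at 223 ± 25.9 against 227 CPM (-0.03, adjusted p = 0.979). TCR signalling genes had 1 of 21 down, Junb at -0.69, and 0 up (8 and 0 adjusted over the list alone; adjusted p = 8.73e-08, and 0.453 with an estimated correlation). Interferon gamma and antigen presentation genes had 0 of 36 called by edgeR over all genes or adjusted over the list alone, with a median of 0.22 (adjusted p = 0.00152, and 0.395 with an estimated correlation). In all 31 genes passed, 9 higher and 22 lower, and 10 of 19 lists, of which 0 held with an estimated correlation. The count was 497 without untreated replicate 1, 509 without untreated replicate 2, 47 without combination replicate 1 and 16 without combination replicate 2, and 5 with no filter on low counts.

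To ask whether CD8 and CD4 conventional T-like cells responded differently to the combination, the difference of their changes was tested with the library as a block. Pdcd1 rose by 1.69 in CD4 conventional T-like cells and stood 0.19 higher in CD8 T-like cells. The difference was -1.51 ± 0.21 (SE, n = 2 against 2, adjusted p = 0.00262). Within CD8 T-like clusters alone, its change was 0.78 in cluster 0 (edgeR adjusted p = 0.102) and 2.18 in cluster 2 (0.938 to 3.92 CPM, adjusted p = 0.429). Neither passed, but both lay above the 0.19 of the class, in which the share of cluster 0 differed between groups. Il17a (chromosome 1, 20730905 to 20734496, plus strand), the cytokine interleukin 17A, went from 497 ± 406 to 109 ± 21.3 CPM in CD4 conventional T-like cells (-2.18) and from 4.89 ± 1.97 to 7.21 ± 4.46 CPM in CD8 T-like cells (0.49), a difference of 2.59 ± 0.49 (adjusted p = 0.0221). Il2ra fell further in CD8 T-like cells (-2.41, or -1.71 in cluster 0 alone, against -0.91 in CD4 conventional T-like cells). S100a4, a calcium-binding protein gene, moved in CD4 conventional T-like cells (-1.53 against -0.06 in CD8). By edgeR 30 of 10690 genes passed, 16 with a more positive and 14 with a more negative change in CD8 T-like cells. The count was 176 without untreated replicate 2, 12 without S. chamaejasme and 15 without combination replicate 1; Il17a did not pass without untreated replicate 1 (1.10), without S. chamaejasme or without combination replicate 1, and with 1 library left out Il2ra passed only without untreated replicate 1. The clusters within each class differed in share between groups as given above.

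**Figure D3:**
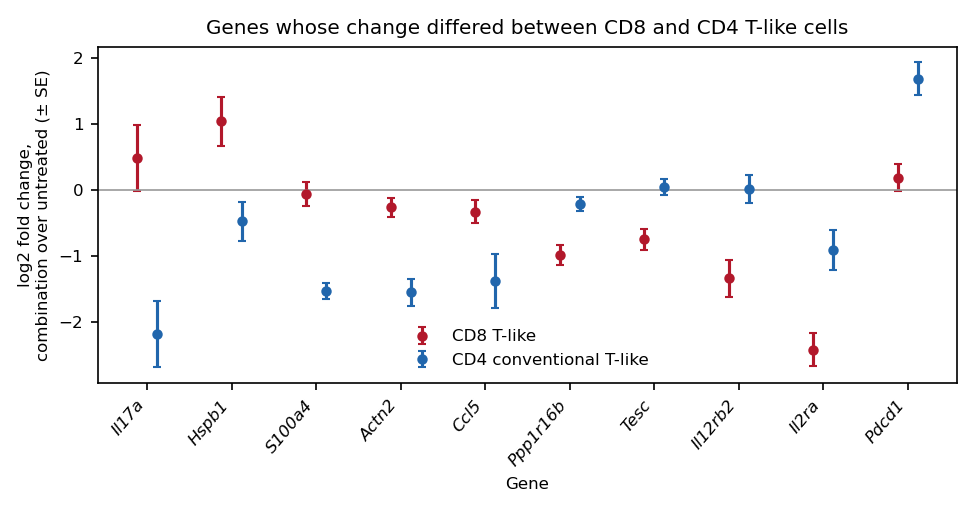
Log2 fold change from untreated to the combination (n = 2 against 2, error bars ± SE) in CD8 T-like and CD4 conventional T-like sums for 10 genes whose changes differed between the classes. Pdcd1 lies at 0.19 in CD8 T-like and at 1.69 in CD4 conventional T-like sums.

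The TCR libraries were used to ask whether clonal expansion differed between groups. At equal numbers of 1144 cells with paired chains per library, 25.7% and 8.44% of the cells in untreated replicates 1 and 2 belonged to clones of at least 2 cells, against 3.48% and 3.99% in the combination replicates. Group means were 17.1% ± 12.2 and 3.74% ± 0.358 (SD, n = 2 each), a difference of -13.3 percentage points (exact permutation p = 0.333, two-sided, the smallest that 2 against 2 libraries allow). The S. chamaejasme library stood at 18.0%; before thinning, 816 of its 3338 paired cells (24.4%, 95% Wilson interval 23% to 25.9%) were in expanded clones. Among CD8 T-like cells thinned to 236 per library the shares were 40.3% and 20.9% untreated, 46.1% with S. chamaejasme and 5.40% and 9.76% in the combination. Within cluster 0, thinned to 139 cells, they were 58.3% and 52.1%, 62.1%, and 28.1% and 39.8%. The largest clones held 15 and 18 cells in the untreated libraries, 45 with S. chamaejasme and 10 and 11 in the combination. The difference was -4.71 without untreated replicate 1, -22.0 without untreated replicate 2 and -5.00 for clones of at least 5 cells.

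**Figure D4:**
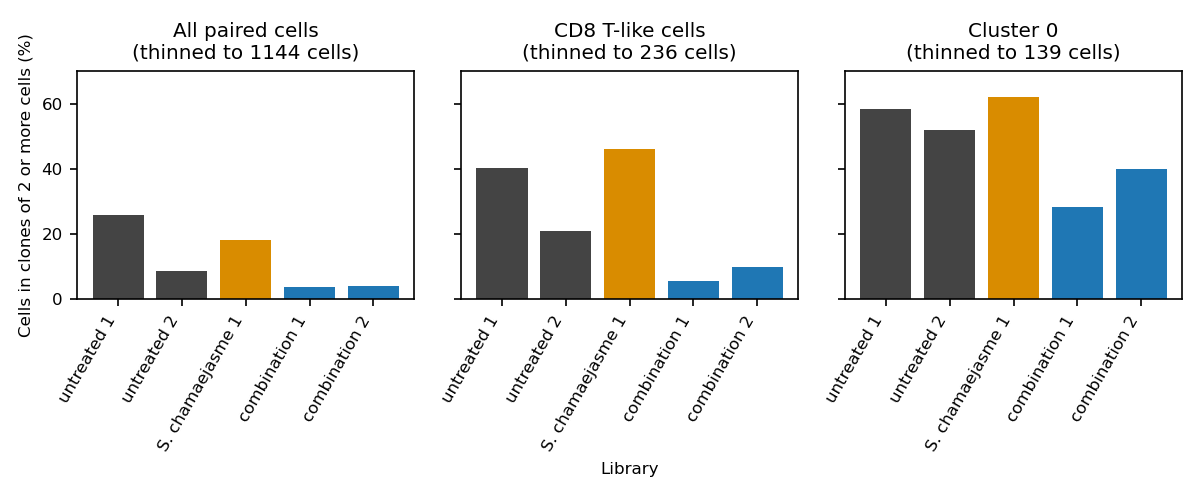
Share of cells with paired TCR chains that belong to clones of 2 or more cells, in percent, per library, for all paired cells, CD8 T-like cells and cluster 0, each thinned to the number of cells shown. In each panel both combination bars lie below both untreated bars, in cluster 0 at 28.1% and 39.8% against 58.3% and 52.1%.

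Within CD8 T-like cells, expanded clones were compared with single-cell clones of the same library (n = 5 libraries). Cxcr6 (chromosome 9, 123806475 to 123811760, plus strand), a chemokine receptor of tissue-resident cells, was higher by 2.63 ± 0.13 (326 ± 68.1 against 53.4 ± 12.5 CPM, adjusted p = 8.18e-13), and Gzmb by 2.30 ± 0.13. Dapl1 (chromosome 2, 59484653 to 59505020, plus strand) had 0 counts in expanded and 1529 in single-cell clones, at least 170-fold lower. The other named genes that were higher were Dkkl1 (3.34), Casp4 (2.78), Grb7 (2.67), Nebl (2.58), Gcnt2 (2.57), Lgals3 (2.49), Il2ra (2.36) and Lilrb4a (2.34). Among those lower were Treml2 (1 count against 382, ratio 0.00784, 95% counting interval 0.000198 to 0.044), Igfbp4 (-5.56), Il6ra (-5.28), Cmah (-4.31), Atp1b1 (-4.14), AB124611 (-4.13), Tdrp (-4.00) and the lymph node homing receptor gene Ccr7 (-3.94). Of the panel, Ifng (2.03), Ctla4 (1.19), Lag3 (1.17), Tigit (1.03) and Pdcd1 (0.98, but -0.15 for clones of at least 5 cells) were higher and Tcf7 (-0.61) lower, while Tox (-0.10) and Prf1 (-0.68, adjusted p = 0.0534) did not pass.

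Naive and memory genes had 15 of 16 lower in expanded clones and 0 higher (16 adjusted over the list alone; adjusted p = 6.33e-54, and 0.0118 with an estimated correlation). Cytotoxicity had 11 of 13 higher and 0 lower (11 and 1 adjusted over the list alone), with Klrc1 at 2.10 (adjusted p = 1.69e-18). Tissue residency had 9 of 12 higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 1.84e-15). Chemokines, costimulation and apoptosis had 8 of 11, 8 of 13 and 12 of 23 higher, each with 2 lower (8 and 2, 9 and 3, and 12 and 2 adjusted over the list alone). With an estimated correlation these 5 lists had adjusted p = 0.0251. Inhibitory receptors had 12 of 14 higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 1.03e-11, and 0.0743 with an estimated correlation), and mitochondrially encoded transcripts 11 of 13 lower (13 adjusted over the list alone; adjusted p = 1.9e-05, and 0.253 with an estimated correlation). By edgeR with the library as a block, 1316 of 6375 genes passed, 717 higher and 599 lower. Expanded clones lay in cluster 0 and almost none in cluster 2 (0% to 0.0958% of its thinned cells), so this comparison is also one between clusters; DESeq2 called 763 genes and clones of at least 5 cells gave 711.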

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

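No test in this part was chosen after its result was seen. The changes of CD8 and CD4 conventional T-like cells between untreated tumours and the combination (S. chamaejasme plus anti-PD-1) were compared by an interaction test in edgeR, and 30 of 10690 genes differed past the threshold (n = 2 against 2 libraries). A positive difference means a more positive log2 change in CD8 T-like cells. Among immune genes the differences included 2.59 for Il17a, -1.51 for Pdcd1, -1.51 for Il2ra and 0.98 for Ccl5. Ccl5, a chemokine gene, changed by -0.33 in CD8 and -1.37 in CD4 conventional T-like cells. Cd8b1 (0.86), Il2rb (0.68) and Il21r (-0.48) passed as well. So did Il10 (adjusted p = 0.0246), with a positive difference that has no definite size. It stood at 0 CPM in untreated and 4.26 CPM in combination CD8 T-like sums. For Il12rb2, a chain of the interleukin 12 receptor, the difference was -1.32, with a fall of -1.33 in CD8 T-like cells and 0.02 in CD4 conventional T-like cells. Hspb1, a small heat shock protein gene, differed by 1.52 (1.04 in CD8, adjusted p = 0.14, and -0.47 in CD4 conventional, adjusted p = 0.342), S100a4 by 1.47 and the actinin gene Actn2 by 1.28 (-0.25 in CD8, -1.54 in CD4 conventional). Tesc differed by -0.77 and Ppp1r16b by -0.75, both lower in CD8 T-like cells (-0.74 and -0.98). Without untreated replicate 2 the count was 176, without S. chamaejasme 12 and without combination replicate 1 15. Il17a was a leading gene of cluster 10, which held 29.5% and 12.1% of the CD4 conventional T-like cells in untreated libraries and 6.98% and 6.62% in the combination. No technical explanation was tested for these genes.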

How the results depend on the processing

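Each cluster taken alone, CD4 conventional T-like cells without clusters 3, 6 and 11, and sums without droplets rich in haemoglobin are tests chosen after the results were seen; the others were planned. Counts of genes stayed within 1.5 times with DESeq2's size factors in edgeR, with doublets kept, at resolution 1.5 and without the haemoglobin droplet (754, 207 and 19 in the 3 CD4 conventional contrasts, against 749, 213 and 24). With only the groups compared, they stayed so in CD8 and CD4 conventional T-like cells. The cause of moved counts was not tested, but the design bears on fits between groups with a library left out. Without an untreated library, only the combination pair shows spread within a group, because S. chamaejasme has 1 library. Without a combination library, only the untreated pair does. The untreated pair differed more (chi-square per gene 15.027) than the combination pair (4.314). The main fits pool these unequal spreads, so counts with a library left out also depend on which pair remains. No paired analysis was possible because the replicate numbers follow the order of the samples and pair no libraries between groups; without the replicate block, expanded against single-cell clones gave 977 genes. Under stricter cells the CD4 conventional T-like class failed the check of its markers, since 1 of its clusters then had 2 Treg markers and none of its own. Other named classes had no value, since gamma delta T cells had 23 cells in 1 library. On simulated sums of equal spread, self-tests recovered 56.6% of 2-fold changes in Treg-like and 73% in CD8 T-like cells between combination and untreated. Changes of that size can thus be missed, and the rates in the real data may differ.

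In CD8 T-like cells, the 442 genes between combination and untreated became 936 with no filter on low counts, 129 with DESeq2, 285 with the TCR and coreceptor gate, 280 in cluster 0, 172 in cluster 2, and 139 (without combination replicate 1) to 1597 (without untreated replicate 2) with 1 library left out, with 1001 without untreated replicate 1 and 229 without combination replicate 2. For S. chamaejasme against untreated, 180 became 732 with no filter, 86 with DESeq2, and 162 to 1406 with 1 library left out (1406 without untreated replicate 1, 1100 without untreated replicate 2). Between combination and S. chamaejasme, 131 became 541 with no filter, 80 with DESeq2, 208 with the gate, and 102 to 1099 with 1 library left out (1099 without untreated replicate 2, 1096 without untreated replicate 1).

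In CD4 conventional T-like cells, the 749 genes between combination and untreated became 2054 with no filter, 419 with DESeq2, 489 with the gate, 68, 262, 134, 111, 74 and 103 in clusters 3, 4, 6, 8, 10 and 11, 486 without clusters 3, 6 and 11, and 207 to 2513 with 1 library left out (207 without combination replicate 2, 251 without combination replicate 1, 2301 without untreated replicate 1, 2513 without untreated replicate 2). For S. chamaejasme against untreated, 213 became 1462 with no filter and 136 to 2429 with 1 library left out (136 without combination replicate 2, 1940 without untreated replicate 2, 2429 without untreated replicate 1). Between combination and S. chamaejasme, 24 became 557 with no filter, 89 with DESeq2, 105 with the gate, and 45 to 1157 with 1 library left out (45 without combination replicate 2, 98 without combination replicate 1, 1089 without untreated replicate 2, 1157 without untreated replicate 1).

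In Treg-like cells, the 170 genes between combination and untreated became 0 with no filter (edgeR, 1609 at an unadjusted p under 0.05), 34 with DESeq2, 74 with stricter cells, 64 at resolution 0.6, 15 with the gate, 61 with only the groups compared, 51 in cluster 9, 37 in cluster 12, and 28 to 1110 with 1 library left out (28 without combination replicate 1, 38 without combination replicate 2, 61 without S. chamaejasme, 476 without untreated replicate 2, 1110 without untreated replicate 1). For S. chamaejasme against untreated, 111 became 7 with no filter, 59 with DESeq2, 15 with the gate, and 81 to 967 with 1 library left out (518 without untreated replicate 2, 967 without untreated replicate 1). Between combination and S. chamaejasme, 31 became 5 with no filter, 20 at resolution 0.6, 6 with the gate, and 16 to 509 with 1 library left out (16 without combination replicate 2, 47 without combination replicate 1, 497 without untreated replicate 1, 509 without untreated replicate 2).

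Expanded against single-cell clones gave 763 genes with DESeq2 and 711 for clones of at least 5 cells, against 1316. The 30 genes of the interaction became 107 with no filter and 12 to 176 with 1 library left out (12 without S. chamaejasme, 15 without combination replicate 1, 176 without untreated replicate 2). Class shares had 0 to 2 classes past the threshold with 1 library left out (2 without untreated replicate 2). The difference in expanded clones kept its sign under every alternative run, from -4.71 to -22.0 points with 1 library left out (without untreated replicates 1 and 2), and was -13.1 for the TRB chain alone, -13.1 for the authors' clonotype identifier, -5.00 for clones of at least 5 cells, -10.9 not thinned, -23.0 in CD8 T-like cells and -10.5 in CD4 conventional and Treg-like cells. Of 76 lists called over the 9 fits, 1 held with an estimated correlation. The 2 residual degrees of freedom of these fits all but fixed that outcome, so it decides little. Some of the 76 calls were lost whichever library was left out. With 1 library left out 71 to 94 lists were called over these fits, except that without S. chamaejasme 3 fits could be made and gave 26 against 24; in each case 0 lists were called in the opposite direction.

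For named genes past the threshold and reported here, leaving out a library gave 1412 values that stayed past it and 202 that did not, with 0 reversed. Genes named by size of change were chosen for having no overlap between the libraries of the groups. This all but fixes their sign when a library is left out, so the 0 reversed says little for them. Of the values in single clusters or without clusters 3, 6 and 11, 143 stayed past, 277 did not and 28 reversed; other alternatives gave 2396, 280 and 6. None of the reversed values passed the threshold, and the cause was not tested. In CD8 T-like cells of cluster 2, Tigit stood at 0.069 and Klrc1 at 0.98. In CD4 conventional T-like cells between combination and untreated, the values were -0.22 for Myo6, 0.43 for Cd44, 0.074 for Ahr, 0.83 for Atf3 and 1.46 for Irf4 in cluster 3; 0.43 for Ahr, -0.14 for Fos and 0.36 for Irf4 in cluster 4; 0.091 for Cd44, 0.85 for Slamf1 and 0.060 for Litaf in cluster 6. They were 0.42 for Il17f, 0.25 for Ccr4 and 1.25 for Cxcr6 in cluster 8, and 0.066 for Il17f, 0.010 for Il21, 0.062 for Cxcr6, -0.29 for Rtp4, 0.27 for Litaf, 0.091 for Atf3 and 0.086 for Hspa1b in cluster 10. Cluster 11 gave -0.020 for Tgtp2, 1.36 for Irf4, -0.15 for Sdhc and 0.17 for Bcl2a1b, and the gate gave 1.67 for Apoe. In Treg-like cells, Areg was at -0.065 in cluster 12 between combination and untreated. With the gate, Il22 was at -10.76 and Ccl4 at 2.66 for S. chamaejasme against untreated, and Il22 at 1.68 between combination and S. chamaejasme; with doublets kept, Ccl4 was at 0.65. Pdcd1 was at -0.15 in clones of at least 5 cells.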

Other observations

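The comparison within single clusters, the test of cluster shares behind the CD8 changes, the test for free haemoglobin RNA and the interval over clones are tests chosen after the results were seen. Within cluster 0, the CD8 T-like cells with granzyme and chemokine transcripts, the combination went with more Fos, an immediate early gene (1.55 ± 0.15 SE, from 377 to 1111 CPM, n = 2 against 2, edgeR adjusted p = 2.02e-05). Other genes of the immediate early list stood lower there, Nr4a3 at -0.88 (adjusted p = 0.0206), Fosb at -0.60 (adjusted p = 0.0633) and Atf3 at -1.22 (adjusted p = 0.109), and the heat shock gene Hspa1a rose (0.87, adjusted p = 0.0252); Fos, Fosb and Atf3 are also on the dissociation list. Cluster 0 further had more Lag3 (1.20, adjusted p = 0.019) and Tox (1.10, adjusted p = 0.0101), while other genes of inhibitory receptors did not pass there: Havcr2 (1.31 CPM against 7.91 untreated, adjusted p = 0.217), Tigit (-0.22, adjusted p = 0.573), Pdcd1 (0.78, adjusted p = 0.102) and Ctla4 (0.43, adjusted p = 0.128). Tap2 (1.10), Tapbp (1.17) and Psmb9 (0.66), genes of antigen presentation, rose there, as they did in cluster 2 (0.74, 0.98 and 0.69). Gzmb fell in cluster 0 by 0.99, from 1466 to 739 CPM (adjusted p = 0.0102), while Ifng stood at 352 against 303 CPM (0.22, adjusted p = 0.49). The inhibitor of NF-kappaB Nfkbia fell in both clusters (-1.01 and -0.75), as did the cell death gene Bbc3 (-1.97 and -0.88).

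Other cytokine and receptor genes passed the threshold in the helper and Treg-like classes. In CD4 conventional T-like cells of the combination, Il17f fell from 65.4 ± 9.38 to 25.2 ± 9.68 CPM (adjusted p = 0.0208) and Il21, made by follicular helper cells, from 20 ± 1.76 to 10.5 ± 2.43 CPM (adjusted p = 0.0307), relative to untreated tumours (n = 2 against 2). Il17f did not fall within cluster 10, which it leads (0.066, adjusted p = 0.941), or cluster 8 (0.42, adjusted p = 0.492), and the share of cluster 10 was lower in the combination, so fewer such cells remain a candidate cause. Il21 stood at -0.97 in cluster 8 (adjusted p = 0.0404) and 0.010 in cluster 10. The T cell cytokine list there had 1 of 16 up and 4 down (2 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.0664, and 0.455 with an estimated correlation), with a median of -0.47 against a mean of 0.10. In Treg-like cells of the S. chamaejasme library (n = 1 against 2), the chemokine receptor gene Cxcr6 (1.85), the inhibitory receptor gene Cd200r1 (1.61) and the interleukin 7 receptor gene Il7r (1.08) rose, and Satb1 (-1.05) and Tnfsf8 (-1.24) fell. Cluster 1, with Xcl1, Fcer1g and Trgv2, held 9.32% of the cells of the S. chamaejasme library and 0.980% to 2.71% of the others.

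The changes in CD8 T-like cells between combination and untreated were weighed against 2 technical explanations. Shares of clusters 0 and 2 alone would leave little change within each cluster. The called genes kept a median change of 0.823 in cluster 0 and 0.613 in cluster 2 in the direction called. The smaller ratio to the class was 0.726, and 432 of 434 and 403 of 419 genes kept their direction. These genes were chosen by their change in sums of the same cells, which by itself raises such values. No uncalled genes were compared, so the set cannot decide on cluster shares. Tests over all genes within each cluster, given above, did not use that choice and called genes in both clusters. This argues against shares of clusters 0 and 2 as the whole cause. Ly6a is an exception in cluster 0 (0.04), as is Cd28 (-0.16). Further exceptions in clusters 0 and 2 are Tigit (-0.22 and 0.069), Cxcr6 (-0.35 and -0.29), Klrc1 (-0.47 and 0.98) and Cd44 (-0.36 and -0.28). Finer mixtures within clusters stay open. Depth differed too, from 1945919 to 4495517 UMIs, and after thinning every sum to the smallest, 99.5% of called genes kept at least 0.5 times their change, but thinning leaves the expected fold unchanged, and 98% of 440 uncalled genes did the same, so this outcome was fixed in advance and decides nothing; 264 genes were called after thinning. Depth, a batch that follows the groups and the treatment itself cannot be told apart.

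The lower share of CD8 T-like cells in expanded clones in the combination could follow from fewer cells of cluster 0, in which expanded clones lie. Within cluster 0, at 100 cells per library, the lowest untreated library was 14.2 points above the highest combination library, but the 95% interval over 2000 redraws of clones runs from -3.19 to 25.2. Fewer cells of cluster 0 and fewer expanded clones within it therefore cannot be told apart here. Among CD8 T-like cells the difference was -23.0 points, with an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow.

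Haemoglobin transcripts in the S. chamaejasme library made up 652 CPM (95% interval 637 to 668) of the CD4 conventional T-like sum, and 0 UMIs were found in the CD8 T-like and Treg-like sums, which allows up to 1.18 and 2.21 CPM. Free RNA would reach all classes alike, and the lower bound of the first is 288-fold above the highest upper bound of the others, which argues against it. All 6899 haemoglobin UMIs lay in 2 of 2877 cells (100% in the 10 cells with most). A single droplet held every UMI of Hbb-bs (3963), Hba-a2 (922) and Hbb-bt (762) and 1251 of the 1252 of Hba-a1, so the level of the class and the 288-fold gap rest on 1 droplet. This is consistent with a droplet that holds a red blood cell beside a T cell, as a hypothesis. No biological explanation was tested for this pattern.

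Contaminant lists with fewer than 5 measured members were not tested: B cell, tumour epithelial and stromal lists in every class, and myeloid and erythroid lists in CD8 T-like and Treg-like cells. In CD8 T-like cells between combination and untreated, the myeloid gene Ctss rose from 34.5 ± 3.62 to 63.9 ± 3.69 CPM (0.88, n = 2 against 2, edgeR adjusted p = 0.00917) and Cd74 stood at -1.69 (adjusted p = 0.204), while the B cell gene Ighm stood at 0.52 (adjusted p = 0.232), the epithelial gene Epcam at -1.10 (adjusted p = 0.198) and the endothelial gene Pecam1 at 0.20 (adjusted p = 0.616).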
